A study of Mus musculus with 2 samples.

How the data were processed

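Naive CD8+ T cells with low CD44 and CD25 were sorted from mice with a T cell deletion of Bcl11b and from wild-type mice of the C57BL/6 strain, to more than 90% purity per the labels. Total RNA was extracted with Trizol and columns, amplified linearly with an Agilent kit and labelled chemically with a Kreatech ULS kit, per the labels' protocols. Each of 2 Agilent whole-genome mouse arrays carried knockout RNA in Cy5 and wild-type RNA in Cy3. The labels call the pairs biological replicates; they do not say how many mice gave each sample. Scans were quantified with Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes.

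The deposited scanner files give, per spot, the mean signal and the local background of each channel as linear intensity values, with no normalisation, per the file headers. They also hold log10 ratios of red over green, made by the scanner software after its own background subtraction and dye normalisation, per the file headers. A deposited value table holds 1 column of log10 ratios per array. It matched the scanner software's log10 ratio to within 0.005 at every spot, which settles its scale and direction, and its columns had medians of 0 and 0. Both arrays lay on the same slide and were scanned together, so there was no batch to test.

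The ratios used here were computed from the intensities with limma 3.58.1 in R 4.3.3. Background was corrected with normexp (offset 50) on the mean signals and median local backgrounds, and log2 ratios were normalised within arrays by loess, with control and flagged spots at weight 0. Those spots were then left out and spots of a probe averaged. Local background was low against the unspecific signal: the median local background was 45 (Cy5) and 35 (Cy3) on array 1, whereas negative control spots had medians of 985 and 1087. On array 2 the negative controls had 1865 (Cy5) and 1120 (Cy3). Dim genes therefore have ratios pulled towards 0.

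A probe was kept if well above background in the same channel on both arrays, and the brightest probe stood for its gene, leaving 9273 genes. Of 41174 gene probes, 24375 were named through their accession in the RefSeq table of GRCm38.p6, 6301 by a current symbol and 2426 by an older symbol; 8072 kept the name in the files. Coordinates are those of the array design (mm8 per the file headers). Of 566 entries in the 23 gene lists, 417 were measured.

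Mean log2 ratios were tested with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. With 2 arrays, eBayes estimated an infinite prior number of degrees of freedom, so every gene shared a standard error of 0.50 and the smallest passing ratio was 1.68 in size. Lists with at least 5 measured genes (22) were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation, with fry, and by the percentile of the list's median among 10000 random lists matched on intensity. With 2 arrays, the test with an estimated correlation and fry have 1 residual degree of freedom, so almost no list can pass them. Errors are standard deviations between the arrays. Where a genotype was not well above background on either array with any probe of the gene, the difference is given as "at least N-fold". It compares the bright channel's mean with, per array, the higher of the lowest signal among probes well above background and the dim probe's own, on log2 channel values after loess and Aquantile normalisation.

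The fit was tested on simulated ratios of 9273 genes with 200 changed. With heavy-tailed noise resampled from the arrays' differences, 5.0% of 2-fold, 73.2% of 4-fold and 96.8% of 8-fold changes were recovered. On average 26.6 unchanged genes were called, and 9.75 with no gene changed. With normal noise 4.6 unchanged genes were called, so the calls hold more false ones than the threshold alone would give. A simulated list of genes raised 2-fold was called in every simulation. Noise was drawn independently for each gene and array, without the part that the arrays share. The simulations therefore do not show how the tests behave with correlated list members or a shared dye effect.

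The following rule for named genes, the gene lists, the fit and most alternatives were fixed before the data were examined. Bcl11b is named first. Then come the 12 highest and 12 lowest mean ratios among passing genes with the same sign on both arrays and both channels well above background on at least 1 array. Free places go to non-passing genes that meet the same conditions on sign and background, ranked by the smaller of their absolute ratios; accession, clone and predicted names are passed over. Up to 4 genes per direction with the largest lower bound follow, and up to 4 members of each list with the largest ratio among those passing or, failing that, among those with the same sign on both arrays. Alternatives changed the background correction, the normalisation within and between arrays, the filter, the choice of probe, the moderation and the thresholds, used the scanner's ratio or the value table, and left out each array in turn. Some list members that the rule names are not reported here. List members named beyond this rule were chosen after their values were seen. Normexp on the negative control spots, and list members at their lower bound, were added after seeing the data.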

Results

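Gene expression was compared between naive CD8+ T cells lacking Bcl11b and their wild-type counterparts. Bcl11b is a zinc-finger transcription factor of the T cell lineage. In the knockout mice, floxed Bcl11b alleles are excised by an iCre recombinase driven by the distal Lck promoter, which is active late in T cell development. RNA of sorted CD8+ cells with low CD44 and CD25 was hybridised on 2 two-colour arrays, each with a knockout sample in Cy5 and a wild-type sample in Cy3. The labels call the arrays biological replicates 1 and 2, and they form 1 group of ratios with n = 2. Both arrays carried the dyes the same way round, so a dye effect of a gene cannot be told apart from the effect of the knockout. On array 1, 17276 of 43379 gene spots were well above background in the knockout channel and 10739 in the wild-type channel. On array 2 the counts were 10955 and 13446. Y-linked Ddx3y and Eif2s3y were well above background in the knockout only on array 1 and in wild type only on array 2. Only 2 arrays set the precision, with 1 residual degree of freedom per gene.

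Bcl11b itself was lower in the knockout on both arrays, at a log2 ratio of -1.45 on array 1 and -1.73 on array 2. The mean was -1.59 ± 0.19 (SD, n = 2), a 3.01-fold lower signal. It did not pass the test across all genes (adjusted p = 0.075, limma). This value came from the brighter probe, annotated by the array design on mm8 chromosome 12 from 108363444 to 108363503, minus strand. A second probe, on chromosome 12 from 108358529 to 108358588, gave -0.35 on array 1 and -2.32 on array 2. No genome was used here to place the probes against the floxed exon, and a probe outside it would not check the deletion.

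Across 9273 measured genes, 138 passed adjusted p 0.05, 115 of them higher and 23 lower in the knockout. With each array centred on its median in place of loess, 63 genes were higher and 1 was lower. The genes that were high on both arrays included receptors and adaptors of natural killer (NK) cells and genes of macrophages, such as Fcer1g, Cd244a, Klrb1c, Adgre1 and Csf1r. Ctse, which encodes the aspartic protease cathepsin E, had the lowest mean ratio and was low on both arrays. The log ratios of the arrays correlated weakly across genes (Pearson r = 0.29, Spearman rho = 0.32; genes are not independent replicates). Array 1 was far more variable: 2504 genes exceeded 2-fold there and 263 on array 2. On both arrays, 104 genes were over 2-fold higher, where independent lists would share 38.4, and 21 were over 2-fold lower, where 4.78 would be shared. With the log ratio of the scanner software the split turned to 263 higher and 331 lower, and with median centring it was 333 and 8. The fit gave every gene the same standard error (0.50 on the log2 scale), so the test ranked genes by their mean ratio alone. It therefore called genes that moved on array 1 only: 19 of the 138 had opposite signs on the arrays, while 52 higher and 7 lower genes were past 2-fold on both. No gene passed after the log ratios were scaled to the same spread on both arrays (901 at an unadjusted p under 0.05, limma). The prior degrees of freedom were then 4.89 and no longer infinite, and 904 genes had such an unadjusted p without scaling.

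**Figure D1:**
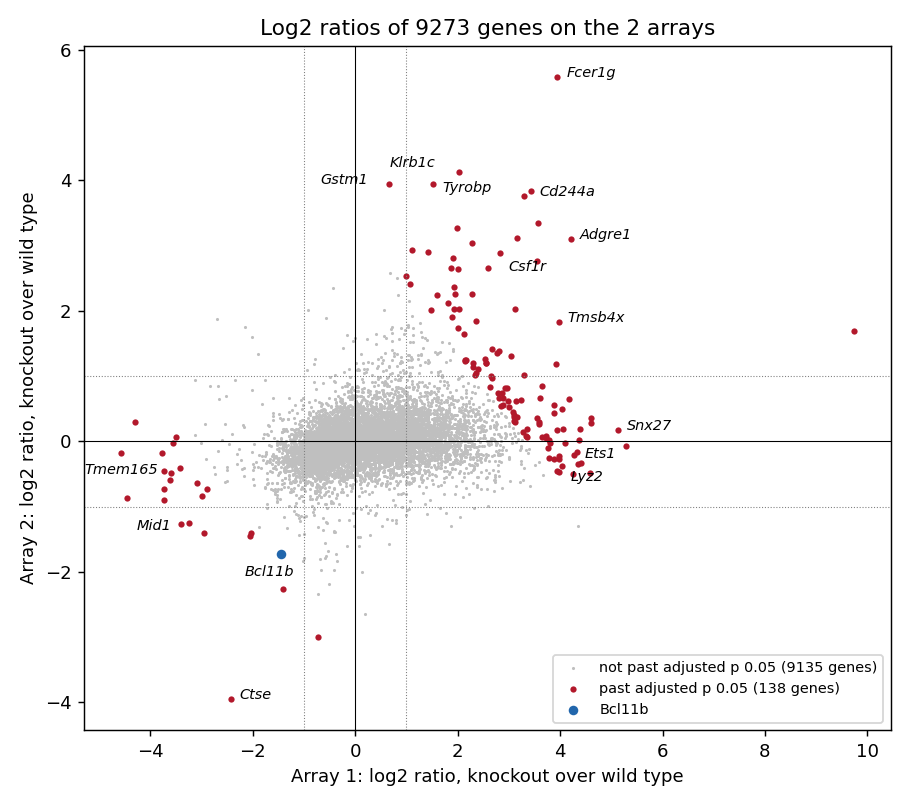
Log2 ratios (knockout over wild type) of 9273 genes on array 1 (x axis) and array 2 (y axis); red points are the 138 genes past adjusted p 0.05, the blue point is Bcl11b, and dotted lines mark 2-fold. Fcer1g and Ctse lie far out on both axes, whereas Snx27 (5.13 and 0.18) and Lyz2 (4.03 and -0.38) are far from 0 on array 1 only.

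Among genes well above background in wild type on at least 1 array, the membrane proteins Cd9 and Cd81, both tetraspanins, rose in the knockout. In wild-type cells Cd9, Cd81, Klrb1c, Klrc2, Itgax, Snx27 and Vamp7 were well above background on array 2 only and Gstm1 on array 1 only, so the size of their change rests in part on a dim channel. The same limit holds for Anxa2, Bcl6, Casp9, Ets1, Ly86, Lyz2 and Ywhaz below, which were well above background in wild type on array 2 only. Cd9 had a log2 ratio of 3.15 ± 0.55 (SD, n = 2; adjusted p = 2.69e-07) and Cd81 one of 2.58 ± 0.77 (adjusted p = 0.000103). The NK receptor gene Klrb1c, which encodes NK1.1, rose by 3.07 ± 1.49, and the signalling adaptor Tyrobp (DAP12) by 2.73 ± 1.71. Klrc2, a lectin-like receptor of the NKG2 family, rose by 2.32 ± 0.45. The integrin gene Itgax (CD11c) rose by 2.27 ± 0.02. Tmsb4x, an actin-binding peptide, was at 3.97 on array 1 and 1.83 on array 2. Gstm1, a glutathione transferase, was at 0.65 on array 1 and 3.95 on array 2. The remaining 4 of the 12 highest passed on the strength of array 1: Snx27 (5.13 and 0.18), Vamp7 (4.60 and 0.37), Ptma (4.18 and 0.64) and Gvin1 (4.04 and 0.50). The second measured probe of Ptma gave 0.56 and -0.26, and another probe of Snx27 gave 0.68 and 0.29.

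For some genes the wild-type channel was not well above background on either array, which leaves only a lower bound, open to dye bias. The largest belonged to Fcer1g, the signalling chain shared by Fc receptors and NK receptors, which was at least 20.6-fold higher in the knockout by its brighter probe (adjusted p = 5.17e-18). Its second probe, well above background in the knockout on both arrays, gave 1.45 and 4.14, a mean under that bound. Cd244a, the receptor 2B4, was at least 6.45-fold higher by its brightest probe (adjusted p = 6.91e-10), while another, well above background in the knockout on array 2 only, gave 0.24 and 1.18. Bmp7, a secreted factor of the TGF-beta family, was at least 5.92-fold higher by its brighter probe, and a second probe, well above background in the knockout on both arrays, gave 1.03 and 2.41. The complement gene C1qc was at least 4.37-fold higher. In the other direction, Amh was at least 2.83-fold lower (adjusted p = 0.0415), with the knockout channel not well above background. Pinlyp (at least 2.19-fold lower), Tmem119 (at least 2.19-fold) and Ecel1 (at least 2.05-fold) did not pass.

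Of the lower genes, Ctse had the lowest mean log2 ratio, -3.19 ± 1.07 (SD, n = 2; adjusted p = 1.85e-07), with -2.43 on array 1 and -3.95 on array 2. In the knockout Ctse, Grin2d, Tmem165 and Mast4 were well above background on array 1 only, so their size on array 2 is uncertain. Mid1, an X-linked ubiquitin ligase bound to microtubules, was at -3.39 and -1.27. Slc16a6, a monocarboxylate transporter, was at -1.41 and -2.26, and Grin2d, a glutamate receptor subunit, at -2.05 and -1.45. Of the lower genes that the naming rule takes, the other 7 that passed had most of their change on array 1: Tmem165 (-4.58 and -0.17), Tfam (-3.62 and -0.60), Ptms (-3.59 and -0.49), Syn1 (-3.43 and -0.41), Mast4 (-3.09 and -0.64), Tagln (-3.56 and -0.02) and Khsrp (mean -1.92, with -0.84 on array 2). Probes of these genes disagreed in part. A second probe of Tmem165, on the opposite annotated strand, gave 1.64 and -0.31, and a second probe of Tfam gave 0.67 and -0.21. A second probe of Ptms, not well above background in wild-type cells, gave 1.04 and 0.31, and another such probe of Slc16a6 gave 0.64 and -0.10. Rpl4, the next gene by the smaller of its ratios, stood at -1.12 on both arrays and did not pass (adjusted p = 0.373).

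NK cell receptors and adaptors rose as a list, with the highest mean over both arrays of the 22 lists; myeloid markers and T lineage factors were higher on array 1 and NK identity markers on array 2. Of 16 measured members, 8 rose, none fell and 8 did not pass, and 13 were above 0 on both arrays. The mean log2 ratio of the list was 1.73 ± 0.53 (SD, n = 2), with 1.36 on array 1 and 2.11 on array 2 (camera adjusted p = 1.36e-22; adjusted p = 0.697 with an estimated correlation). Fcer1g, Cd244a, Klrb1c and Tyrobp led it, followed by Klrc2, Cd7, Klra7 and Klrc3. Adjusted over the list alone, 10 members passed, the added ones being Klrk1 (1.54 ± 0.39) and Cd160 (at least 2.09-fold higher). Ncr1, which encodes NKp46 and is restricted largely to NK cells and related innate lymphocytes, was at 0.33 ± 0.74 and did not pass. The 6 members with only a bound, set at it, gave a list mean of 1.52, below that of NK identity markers treated the same way (1.61). No list passed with an estimated correlation, but that test has 1 residual degree of freedom and could hardly pass any list. Heat shock, activation and gamma delta genes failed it with estimated correlations (-0.029, -0.013 and -0.2) under the preset 0.01. The estimates were above the preset for NK receptors (0.533), T lineage factors (0.543), NK identity markers (1) and myeloid markers (0.121). For these lists the preset may be too low and the camera p too small, though each estimate rests on 1 residual degree of freedom. Myeloid markers moved the same way (mean 1.35), and receptor genes of the Klra and Klrc families have near-identical copies that a probe can also detect.

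**Figure D2:**
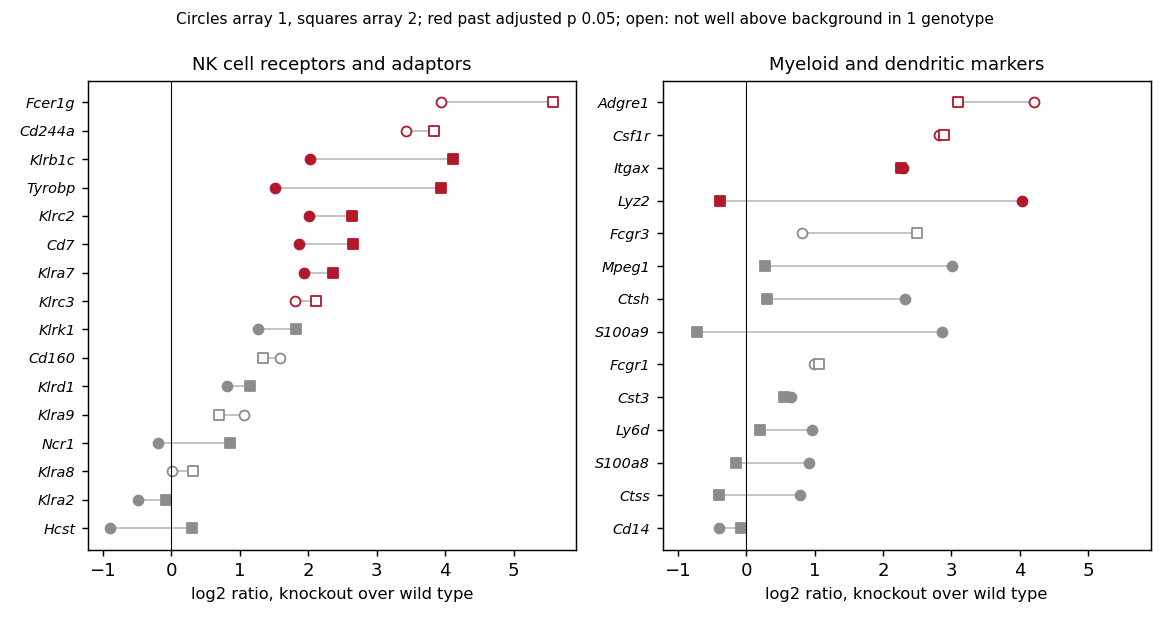
Log2 ratios (knockout over wild type, x axis) of the measured members of 2 gene lists on array 1 (circles) and array 2 (squares); red genes passed adjusted p 0.05, and open symbols had 1 genotype not well above background on either array. Fcer1g had 3.95 on array 1 and 5.58 on array 2, while Lyz2 had 4.03 on array 1 and -0.38 on array 2.

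Cytolytic and effector genes did not follow as a group (17 measured, mean log2 ratio 0.35 ± 0.09, camera adjusted p = 0.2). Ccl3, a chemokine, was the only one to pass, at least 1.93-fold higher (adjusted p = 0.0174). Adjusted over the list alone, 4 rose (Ccl3, Xcl1, Srgn and Ccl5) and 1 fell, Gzmm, which was at 0.20 on array 1 and -2.64 on array 2. The pore-forming protein gene Prf1 was at -0.55 and -1.25 and did not pass. Genes of activation and memory rose as a list (22 measured, mean 0.67 ± 0.06, camera adjusted p = 0.000408; adjusted p = 0.697 with an estimated correlation). Tnfrsf9, the costimulatory receptor 4-1BB, was at least 2.61-fold higher by its brighter probe (a second gave 1.70 and 0.67), and Anxa2, an annexin, rose by 2.16 ± 1.05. The other 20 members did not pass over all genes, and 6 rose when adjusted over the list alone. Cd44, one of the markers used in the sort, was at 1.58 and 0.36, and Ly6c1 at -0.97 and -1.15, neither past the threshold. Heat shock genes (mean 0.62) and myeloid markers (mean 1.35) moved the same way as the activation list.

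Genes of the naive state and quiescence did not shift as a list (21 measured, mean 0.36 ± 0.77, camera adjusted p = 0.172). The arrays gave opposite means, 0.90 and -0.19. Btg1, an antiproliferative factor, rose over all genes (1.73 ± 1.27), although its second probe gave 0.49 and 0.58. Adjusted over the list alone, 3 rose, and 1 fell, the lymph node homing receptor gene Ccr7 (-1.72 and -0.96). Transcription factors of the T lineage rose as a list (24 measured, mean 0.95 ± 0.86, camera adjusted p = 5.41e-09; adjusted p = 0.697 with an estimated correlation), with 1.55 on array 1 and 0.34 on array 2. Over all genes 4 rose and 20 did not pass, and 8 rose adjusted over the list alone. Id2, an inhibitor of E proteins, rose by 1.75 ± 0.77 and Bcl6 by 1.70 ± 0.92. Ikzf2 (Helios) passed with a probe not well above background in wild-type cells on either array, so its size is open; a probe that was well above background in both genotypes on array 1 gave -0.003 there. Ets1 was at 4.37 on array 1 and 0.02 on array 2, and its other probes gave 0.81 to 2.80 on array 1 and -0.06 to 0.33 on array 2. Myeloid markers (mean 1.35), NK identity markers (1.67) and heat shock genes (0.62) moved the same way, and housekeeping genes were also higher on array 1 (0.84) than on array 2 (-0.04).

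The T cell receptor and coreceptor genes had no member past the threshold (16 measured, mean 0.36 ± 0.38, camera adjusted p = 0.197), also when adjusted over the list alone. Cd8b1 was at 1.11 and 0.93, and Cd8a at 0.79 and -0.28. The scavenger-type surface receptors Cd5 (-0.69 and -1.80) and Cd6 (-0.58 and -1.79) were lower on both arrays without passing, and a second probe of Cd6 gave 0.85 and -1.002. Trat1 was at 1.62 and 0.60, and Cd28, not well above background in wild type, was at least 1.76-fold higher without passing. T cell receptor signalling genes gave a mean of 0.11 ± 0.35 (25 measured, none past, also over the list alone; camera adjusted p = 0.909, with the list placed below the other genes although its mean was above 0). Lcp2 was at 1.59 and 0.13, Rasgrp1 at 1.30 and 0.11 and Dgka at -0.94 and -0.46. Median centring raised the typical gene by 0.64 on the log2 scale and made the mean of Dgka positive.

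No member of the cytokine receptor and JAK-STAT list passed (35 measured, mean 0.32 ± 0.35, camera adjusted p = 0.172), and none did over the list alone. Among members with the same sign on both arrays, the interleukin-18 receptor gene Il18r1 came nearest, at 1.85 and 1.24 (adjusted p = 0.0911), followed by Il7r (2.17 and 0.21), Smad3 (1.84 and 0.47) and Il6ra (-0.64 and -1.18). Chemokine receptors and integrins likewise had no passing member on either count (19 measured, mean 0.23 ± 0.26, camera adjusted p = 0.533). Itgb3 was at 1.04 and 1.32, although a second probe gave -1.03 and 0.13, Cxcr4 at 0.88 and 0.95 and Ccr2 at least 1.34-fold higher. Cell cycle genes gave a mean of 0.36 ± 0.29 with none past on either count (18 measured, camera adjusted p = 0.172), among them Ccnd2 (2.39 and 0.44), Mki67 (1.41 and 0.44), Tyms (1.42 and 0.24) and Pcna (1.84 and 0.01). Other probes of Ccnd2, well above background in both genotypes on both arrays, gave 0.47 and 0.12, and 0.74 and 0.11. Another probe of Tyms gave 2.49 and 0.28. Of 27 apoptosis genes 1 rose on both counts, Casp9 (3.61 on array 1 and 0.67 on array 2; list mean 0.35 ± 0.21, camera adjusted p = 0.161). Interferon response genes gave a mean of 0.10 ± 0.23 with none past on either count (35 measured, camera adjusted p = 0.869). The list's mean was above 0 while camera placed it below the other genes. Oas3 was at 1.35 and 0.58, Ifih1 at 2.02 and 0.06, Isg20 at -1.19 and -0.44 and Igtp at -0.88 on both arrays, the last turning positive with median centring. Immediate early and NF-kappaB genes gave 0.30 ± 0.09 (27 measured, none past on either count, camera adjusted p = 0.209), with Egr1 at 2.00 and 0.63, Egr2 at 1.69 and 0.71, Nr4a2 at 1.61 and 0.66 and Klf6 at 1.89 and 0.36.

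Markers of other cell types were examined because the sort was stated to be more than 90% pure. Myeloid and dendritic markers rose (14 measured, mean log2 ratio 1.35 ± 0.75, camera adjusted p = 5.09e-12; adjusted p = 0.697 with an estimated correlation), with 1.88 on array 1 and 0.82 on array 2. The mean was 0.99 with its 4 bounded members set at their bound. Over all genes 4 rose and 10 did not pass, and 7 rose adjusted over the list alone. Adgre1, a macrophage surface receptor, was at least 3.70-fold higher (adjusted p = 6.63e-10), and Csf1r, the receptor for macrophage colony-stimulating factor, at least 1.93-fold higher. Itgax was at 2.29 and 2.26, and Lyz2, the abundant lysozyme of myeloid cells, at 4.03 and -0.38. NK cell identity markers gave a mean of 1.67 ± 0.73 (8 measured, camera adjusted p = 1.11e-11; adjusted p = 0.697 with an estimated correlation), carried by Fcer1g, Klrb1c and Tyrobp, the 3 that rose on either count. These 3 also stand in the list of NK receptors. Markers of gamma delta and innate-like T cells gave 0.92 ± 0.16 (5 measured, camera adjusted p = 0.0109; adjusted p = 0.697 with an estimated correlation), with Cd163l1, a scavenger receptor, up by 1.91 ± 0.90 and 2 members past over the list alone.

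B cell markers did not pass as a list (11 measured, mean 0.55 ± 0.47, camera adjusted p = 0.0673), and Ly86 was the only member past on either count (3.64 and 0.85). Immature thymocyte markers gave 0.57 ± 0.32 with none past on either count (6 measured, camera adjusted p = 0.161), including Mns1 (0.85 and 0.96), Cd4 (-0.65 and -0.21) and Dntt (0.50 and 0.30). Erythroid and platelet markers gave 0.01 ± 0.03 (5 measured, camera adjusted p = 0.756), with Hba-a1 at 2.56 and 0.30, Gp1bb at -1.71 and -0.57, Car2 at least 1.44-fold higher and Treml1 at -0.95 and -0.31. None of these passed over all genes, and Hba-a1 did over the list alone. The median of that list was -0.32, on the other side of 0 from its mean. Of 4 measured markers of CD4+ and regulatory T cells, too few for a list test, Ikzf2 alone passed (list mean 0.12, median -0.33).

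Among reference genes, heat shock and stress genes rose as a list (17 measured, mean 0.62 ± 0.04, camera adjusted p = 0.00517; adjusted p = 0.697 with an estimated correlation). Hmox1, the haem-degrading enzyme, was the member that passed (1.98 ± 0.06, adjusted p = 0.00957), and 4 passed over the list alone. Ribosomal protein genes gave 0.29 ± 0.08 with none past on either count (32 measured, camera adjusted p = 0.209). Rps3 (1.29 and 1.33), Rps2 (1.02 and 1.24) and Rpl5 (1.23 and 0.83) lay above 0 and Rpl4 below. Other probes went the opposite way, with -1.01 and -0.20 for Rps3 and -0.44 and -0.21 for Rps2. Housekeeping genes gave 0.40 ± 0.62 (13 measured, camera adjusted p = 0.172), with 0.84 on array 1 and -0.04 on array 2. Ywhaz was the only one past on either count, at 3.77 on array 1 and -0.09 on array 2.

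**Figure D3:**
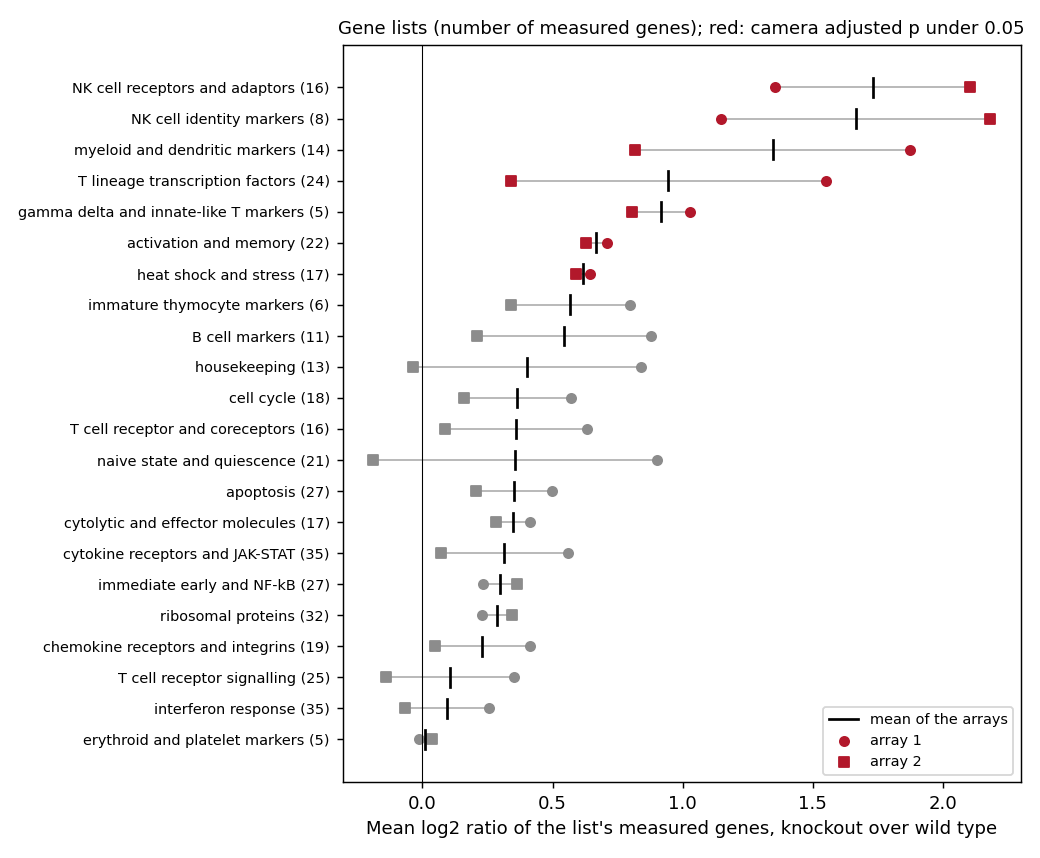
Mean log2 ratio (knockout over wild type, x axis) of the measured genes of 22 lists on array 1 (circles) and array 2 (squares), with the mean of both arrays as a black bar; red lists passed camera adjusted p 0.05 at a preset correlation, and none passed with an estimated correlation (adjusted p = 0.697 for each red list). The test with an estimated correlation has 1 residual degree of freedom, so almost no list could pass it. NK cell receptors and adaptors have the highest mean of both arrays at 1.73, and housekeeping genes sit at 0.84 on array 1 and -0.04 on array 2.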

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

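Normexp on the negative control spots and list members set at their lower bound were chosen after the data were seen; the other alternatives were fixed before. The cause was not tested for any change below, except where fewer genes or arrays entered or where degrees of freedom are given. Each ratio already pairs the knockout and wild-type sample of 1 array, so no other pairing was fitted. Negative control spots were far brighter than the local background, so dim genes are limited by unspecific signal, and each array left alone gives a value with no test. With 2 arrays, a gene's mean always lies within 1 SD of either array, so leaving out an array shows no stability of single genes.

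The 138 genes past adjusted p 0.05 (limma) became 35 with no background correction (33 shared with the 138), 64 with median centring (51 shared; 98.4% higher against 83.3%), 39 with the strict filter (25 higher and 14 lower; 33 shared of 46 tested), 263 with trend and robust moderation (108 shared) and 60 with normexp on negative control spots (43 shared). They became 0 with the scanner's log ratio (602 at unadjusted p under 0.05), 0 with no filter (2478), 0 after scaling between arrays (901) and 0 with the value table (594). At an unadjusted p under 0.05, 904 genes passed. Offset 16 gave 153 (135 shared) and the mean over probes 147 (116 shared). These counts followed the prior degrees of freedom that eBayes estimated. They were infinite where 138 to 153 genes passed, 17.2 to 49.5 where 35 to 64 passed, and 1.96 to 4.89 where 0 passed. Those of the trend and robust fit, with 263 genes, were not recorded. A count of 0 therefore does not by itself show that the ratios had shrunk. Median centring moved the median of all genes by 0.64 on the log2 scale, so its directions are relative to that shift.

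The 125 genes over 2-fold on both arrays (104 higher, 21 lower) became 46 with no background correction (38 and 8), 341 with median centring (333 and 8), 48 with the strict filter (35 and 13) and 519 with normexp on negative control spots (275 and 244). With the scanner's log ratio and with the value table there were 594, and the majority turned (263 higher, 331 lower). A 1.5-fold threshold gave 482 (330 and 152) and a 3-fold one 30 (29 and 1). With 1 array left out, 263 to 2504 genes were over 2-fold. The correlation of the arrays was 0.241 with no background correction, 0.369 with the scanner's log ratio, 0.435 with median centring, 0.332 with no filter, 0.218 with the strict filter, 0.309 with the mean over probes, 0.3695 with the value table and 0.373 with normexp on negative control spots.

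Bcl11b passed at -1.43 (adjusted p = 0.0397) with no background correction and at -1.59 (adjusted p = 0.0391) with the strict filter, which tested fewer genes; under the other processing settings its adjusted p was above 0.05. In the main analysis it passed at an adjusted p under 0.1 and at an unadjusted p under 0.05. Leaving out an array gave -1.73 to -1.45. With median centring Dgka turned to 0.35 and Igtp to 0.18. Leaving out an array gave -0.38 to 4.03 for Lyz2 and -0.095 to 3.77 for Ywhaz, the lower value without replicate 1 in both.

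The 7 gene lists past adjusted p 0.05 became 14 with median centring, 13 with no filter and 3 with a variance trend in camera. They became 0 with an estimated correlation (adjusted p = 0.6965 for each of the 7) and 0 with fry. The variance trend used neither the genes' brightness nor the robust step, so it differs from the trend and robust moderation of single genes. In fry, the adjusted p was 0.4341 for NK receptors and gamma delta markers, 0.426 for activation and heat shock genes, 0.555 for transcription factors and 0.497 for myeloid and NK identity markers. The variance trend in camera gave 0.104 for activation and heat shock genes, 0.0771 for NK identity and 0.188 for gamma delta markers, and the strict filter 0.0792 for activation genes. Among lists that did not pass, the camera direction of T cell receptor signalling turned at adjusted p = 0.970 (scanner), 0.176 (median centring) and 0.623 (no filter). It also turned at 0.806 (mean over probes), 0.891 (variance trend) and 0.969 (value table). That of interferon response turned at 0.970 (scanner), 0.143 (median centring), 0.948 (no filter), 0.891 (trend and robust), 0.969 (value table), 0.922 (negative control spots) and 0.725 (fry). Ribosomal proteins turned at 0.806 (mean over probes) and B cell markers at 0.950 (strict filter). Fry placed T cell receptor signalling (adjusted p = 0.741), interferon response (0.725) and erythroid markers (0.741) upward, where camera placed them downward. This is no turn, since fry compares a list with 0 and camera with the other genes, and these lists had means above 0. Among random lists matched on intensity, the medians of the 7 passing lists lay at percentiles of 99.12 to 100. Lists that did not pass also lay high, such as T cell receptor genes (98.54), B cell markers (99.4) and immature thymocyte markers (98.31). The random lists draw genes independently, so they do not allow for correlation between genes.

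List means moved by more than the spread between arrays as follows. With the scanner's log ratio they were 2.88 (NK receptors), 2.31 (myeloid), 2.54 (NK identity), 1.12 (activation), 0.77 (heat shock) and 1.31 (gamma delta), and with the value table they were 2.88, 2.31, 2.54, 1.11, 0.77 and 1.31. With normexp on negative control spots they were 2.54 (NK receptors), 1.02 (activation), 0.75 (heat shock) and 1.25 (gamma delta). For activation, heat shock and gamma delta genes in turn, median centring gave 1.40, 1.40 and 1.60, no background correction 0.51, 0.51 and 0.75, and no filter 0.60, 0.57 and 0.59. The mean over probes gave 0.55 for heat shock and 1.16 for gamma delta genes, and the strict filter 0.30 for activation genes.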

Other observations

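The tests of NK cells, myeloid cells, macrophages and dye bias were chosen after the results were seen, as were the genes named in the next 3 paragraphs; those of RNA integrity, dim spots and position were written before their values were seen.

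Outside the fixed lists, several signalling genes were over 2-fold higher on both arrays. Tgfb3, a TGF-beta family ligand, was at 2.59 on array 1 and 2.66 on array 2 (at least 2.81-fold, adjusted p = 6.77e-05, limma). Clnk, an adaptor of immunoreceptor signalling, was at 2.02 and 2.03 (at least 2.23-fold), and Klra23, a further Ly49 receptor gene, at 1.60 and 2.24 (at least 3.16-fold). The protease inhibitor gene Serpinb6b was at 2.36 and 1.85. Ctla2a (1.23 and 1.32) and Ctla2b (1.32 and 1.44) did not pass. Of the 104 genes over 2-fold higher on both arrays, 31 stood in a fixed list; of the 21 lower ones, 1 did.

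Of 26 measured transcripts abundant in macrophages, 9 passed, all of them higher. Slc40a1, the iron exporter ferroportin, was at 3.56 and 3.34 (at least 1.95-fold), next to Hmox1 (1.94 and 2.02). Apoe was at 1.94 and 2.26 and Sirpa at 2.12 and 1.64 (at least 1.82-fold), all past the threshold. Vcam1 (at least 2.28-fold higher), Spic (at least 1.90-fold) and Cd5l (0.71 and 1.73) did not pass, nor did Grn (-3.14 and 0.94), Cd14 (-0.40 and -0.08), Ctsz (0.15 and 0.23) and Trf (-0.29 and 0.46).

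Several sex-linked transcripts, which lay outside the 9273 genes, ran opposite ways on the arrays. On array 1 the Y-linked genes Kdm5d (3.20), Eif2s3y (1.99) and Ddx3y (2.30) had positive log2 ratios and were well above background in the knockout only, while Xist was not well above background in either genotype. On array 2 the same probes gave -2.46, -2.98 and -2.04, with Ddx3y and Eif2s3y well above background in wild type only and Kdm5d in neither. There, 3 Xist probes were well above background in the knockout only, at up to 6.90. The labels used here do not give the sex of the mice. A difference in sex between the samples of an array would be confounded with genotype on that array. Second probes of these genes that were not well above background lay nearer to 0, and 3 probes of Y-linked Uty, not well above background either, lay between -0.36 and -0.018 on both arrays.

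Log ratios spread more on array 1 (SD 1.01) than on array 2 (0.41). Degraded wild-type RNA on array 1 would raise ratios at 5' probes, yet the 5'-most minus the 3'-most probe of 2081 genes had a median of -0.13 (95% bootstrap interval -0.17 to -0.10), and -0.03 on array 2 (-0.04 to -0.02), the sign of more degraded knockout RNA, which stays open. Dim spots are argued against by the 2318 brightest genes, where the spread on array 1 was still 2.60 times that on array 2. Position explained 1.22% of the variance on array 1. Also open is a difference between probes of one gene: probe-specific differences made up 52.9% of the variance on array 1 and 34.8% on array 2, although spots of one probe differed by an SD of only 0.10.

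The NK receptor genes, higher on both arrays, could come from NK cells that passed a gate for CD8+ cells, from myeloid cells sharing Fcer1g and Tyrobp, from the dyes, or from a change in the knockout T cells, which the design cannot test apart. The 21 NK receptors taken as largely absent from myeloid cells had a median of 0.94 (interval 0.71 to 1.54) with no background filter. This leans against myeloid cells as the whole source without excluding them. The interval resamples genes, so it leaves out the spread between arrays and a shared dye effect, and near-identical copies count separately. Those of the 21 not measured in the main analysis failed the filter on dim probes. The 11 measured ones, all in a fixed list, had 1.54 (interval 0.88 to 2.26), but only 2 were well above background in wild type on both arrays, so the filter favours high ratios there. For NK cells, 19 abundant transcripts that are not NK receptors were taken, all in a fixed list and 13 well above background in wild type on both arrays. They include the cytokine receptor genes Il2rb, Il18r1 and Il18rap. The median of the 19 was 0.41 times that of the NK receptor and adaptor list (interval 0.26 to 1.05, which includes both outcomes). Gzma was at 0.72 and 0.80 and Prf1 at -0.55 and -1.25. The ratio cannot decide, since several of the 19 were bright in wild type (mean log2 15.57 for Nkg7 and 15.20 for Ccl5). Receptors such as Klrc3 (8.57) and Klra7 (9.55) were dim, though Klrd1 (14.60) was not. The same amount of NK cell RNA raises the ratio of a bright gene less. Dye bias cannot be told apart from the knockout, since 0 of 2 arrays had the knockout in Cy3.

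The macrophage genes, higher on both arrays, may come from macrophages in the knockout sort. A gate on CD8 is meant to leave out cells that lack it. Whether macrophages passed that gate was not tested, since no sort data were examined. The 26 measured abundant macrophage transcripts had a median 0.57 times that of the passing macrophage genes (interval 0.28 to 0.83). This ratio cannot decide. Its divisor holds genes chosen for high ratios in these data, and the 9 of the 26 that passed stand on both sides, which holds it under 1. The 26 transcripts included Apoe and Lyz2, which passed, and Cst3 (0.65 and 0.55), Ctss (0.79 and -0.40) and Grn (-3.14 and 0.94), which did not. Of the 26, 11 were well above background in wild-type cells on both arrays, and 10 stand in a fixed list. Dye bias stays open here as well (0 swapped arrays), as does a change in the knockout T cells.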
